A study of Mus musculus with 24 samples.

How the data were processed

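RNA was sequenced from 3 cell populations sorted from the colonic lamina propria of mice that carry eGFP under control of Nmur1, the gene for a receptor of the neuropeptide neuromedin U (NMU). Per the labels, the populations were group 2 innate lymphoid cells (ILC2) with eGFP, CD4 T cells with eGFP (NMUR1+ below) and CD4 T cells without eGFP (NMUR1- below). The mice had drunk dextran sulfate sodium (DSS, 3%), which injures the colonic epithelium, for 5 days and then water for 3 days, and were injected with NMU or with the vehicle phosphate-buffered saline (PBS) every other day. The labels name 4 mice per treatment, mice 1 to 4 for NMU and mice 5 to 8 for PBS, and give 3 populations for each of the 8 mice, 24 libraries in 6 groups of 4. The series' design text counts 3 mice per treatment. The mouse numbers of the sample labels were used, because they name every library.

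Per the labels' protocols, RNA was extracted with the RNeasy Micro Kit and libraries were made with the NEBNext Single Cell/Low Input kit, which amplifies cDNA and does not mark strand or molecules. Reads were aligned with STAR 2.5.3 to the mouse build mm10, per the submitters' processing notes. The counting program, the annotation and the use of strand are not given in the sources used here. The deposited table holds whole-number counts per gene and library, not normalized, for 27179 gene identifiers under 3 lines of sample labels. The label lines of all 24 columns matched the sample labels, and no column was left unused. Of the identifiers, 25275 (93.0%) were matched to a symbol in the RefSeq table of GRCm38.p6 by their identifier. The other 1904 hold 0.986% of all counts and stayed in the tests without a name. GRCm38 is the assembly behind mm10, and the coordinates printed are those of the RefSeq table, counted from 1. Total counts per library ran from 8485266 to 17854961 with a median of 12468400. Reads are amplified copies without molecular identifiers, so the floors given below cover counting error only. Near-identical gene copies, overlapping genes and antisense pairs, among them T cell receptor and immunoglobulin constant genes and the Bcl2a1 and class II gene families, are uncertain where the counting could split or mix their reads.

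Replicate libraries were compared before they were averaged. The lowest chi-square per degree of freedom between any pair of replicates was 16.55, so no pair agreed within sampling noise and each library counted as 1 replicate. The labels name separate mice, each with 1 library per population. The spread within a group therefore holds that between animals together with that of sorting and library preparation.

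Genes were tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts. Genes were kept by filterByExpr with a minimum count of 10, libraries were scaled by trimmed mean of M values (TMM), and robust quasi-likelihood fits (glmQLFit, glmQLFTest) gave a log2 fold change, its standard error (SE) and a p-value. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05 and no minimum fold. NMU was compared with PBS within each population on that population's 8 libraries. Populations were compared with each other, and NMU effects between populations, in 1 fit of all 24 libraries with a mean for each of the 6 groups. Expression is given as CPM computed by edgeR on TMM-scaled library sizes, as mean ± SD. Where a group had 0 counts in every library, the fold ("at least") is against a floor of 3 counts over the group. Fitted log2 values of such genes depend on the prior count and are no bound. TMM factors ran from 0.719 to 1.16 over the 24 libraries.

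The designs, the genes named and the gene lists were fixed before the data were examined. Nmur1, Areg, Il5, Il13, Il4, Csf2 and Il10 are given in each treatment comparison, and Nmur1, Cd3e, Cd4, Klrg1, Gata3, Il1rl1, Foxp3, Areg, Il5 and Il13 in each population comparison, whatever their test. Another preset gene and 3 genes that the rules below select are not reported here. To these come up to 8 genes higher and 8 lower with the largest log2 fold change among those past the threshold with a mean of at least 10 CPM in the higher group and, in treatment comparisons, no overlap between the libraries or, in population comparisons, the same sign in all 8 mice. Predicted genes, clone names, pseudogenes and receptor V segments were left out of this part, and up to 5 genes per direction were taken for differences between NMU effects. Up to 3 genes per list and direction were also named, and the 5 genes with the smallest p-values where fewer than 5 passed. Gene lists, none chosen on these samples, were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data and with fry, a rotation test of whether the genes of a list move, on balance, one way. Lists needed 3 tested members, and their p-values were adjusted over the lists of a comparison. Members past the threshold were counted after adjustment over all genes and over the list alone.

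The alternatives were DESeq2 (1.42.0), limma voom with sample quality weights, size factors from DESeq2 or upper-quartile scaling in edgeR, no filter, a stricter filter of 10 CPM in 4 libraries, each mouse left out in turn, all 24 libraries in 1 fit for the treatment comparisons, and for the population comparisons only their 16 libraries or the mice of 1 treatment. The mouse was tried as a replicate block wherever a fit holds several populations. Pairing comes from the labels, which name the same mouse for 3 populations. Across 8262 genes, deviations from the group means of NMUR1+ and NMUR1- libraries of the same mouse correlated with a median r of 0.323 (0.0876 to 0.662), those of ILC2 and NMUR1+ libraries with 0.117 (-0.0184 to 0.365) and those of ILC2 and NMUR1- libraries with 0.0644 (0.0114 to 0.445). Genes are not independent replicates. Within a population the mice of the treatments differ, so no block is possible there. Further alternatives were added after seeing the data. Immunoglobulin genes and Jchain (262 genes) were left out of the library sizes, log2 CPM of Jchain and of Lyz2 were used as covariates for RNA of plasma cells and macrophages, libraries with over 20% of their counts in immunoglobulin genes and Jchain (NMUR1+ libraries of mice 1, 4, 5 and 7) were left out, and the NMU ILC2 library of mouse 1 was left out.

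The tests were run on simulated counts drawn from the real libraries' means, in which 200 genes at most were changed by a known fold. In the simulation of NMU against PBS in ILC2 (10720 genes), edgeR recovered 14.1% of the 2-fold and 53.2% of the 4-fold changes, and 9.86% of its calls were false. DESeq2 recovered 30.3% and 67.0% there with 31.1% false calls, and limma voom 10.1% and 45.7% with 8.62%. For NMUR1+ cells (11580 genes) edgeR recovered 13% and 63.5%, and for NMUR1- cells (11880 genes) 34% and 86%. It recovered 53% and 82% for NMUR1+ against NMUR1- cells (13230 genes), and 3% and 51% for the difference between the NMU effects in ILC2 and NMUR1+ cells (13180 genes). Small changes within a population, and in the differences between NMU effects, were therefore mostly below what the tests could detect.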

Results

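RNA counts were obtained for 24 libraries from the inflamed colon of 8 mice, 4 treated with NMU and 4 with PBS. Each mouse gave a library of Nmur1-eGFP+ ILC2, innate lymphocytes that make the cytokines IL-5 and IL-13, a library of NMUR1+ CD4 T cells and a library of NMUR1- CD4 T cells. The 6 groups of population and treatment therefore had n = 4 each. Total counts ran from 8485266 to 13064665 in ILC2 libraries, from 9759943 to 17379633 in NMUR1+ libraries and from 11273585 to 17854961 in NMUR1- libraries. ILC2 libraries held counts for 10778 to 13736 genes, fewer than most NMUR1+ libraries (13154 to 15664) and all NMUR1- libraries (14998 to 15955). Nmur1 is the receptor gene on whose reporter the cells were sorted (gene 14767, protein coding, GRCm38 chromosome 1, 86386242 to 86389361). It averaged 233 ± 56.9 CPM in ILC2, 41.2 ± 24.2 CPM in NMUR1+ and 4.38 ± 2.56 CPM in NMUR1- cells (SD, n = 8). The eGFP transcript was not analysed here.

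Immunoglobulin RNA was found in all 24 libraries. Immunoglobulin genes and Jchain, products of plasma cells, took 0.785 to 30.4% of the counts in NMUR1+ libraries and 0.148 to 5.59% in NMUR1- libraries. Within ILC2 they took 0.027 to 0.869% in the 4 NMU libraries and 0.666 to 7.94% in the 4 PBS libraries. The NMUR1+ libraries of mice 1, 4, 5 and 7 lay above 20%.

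**Figure D1:**
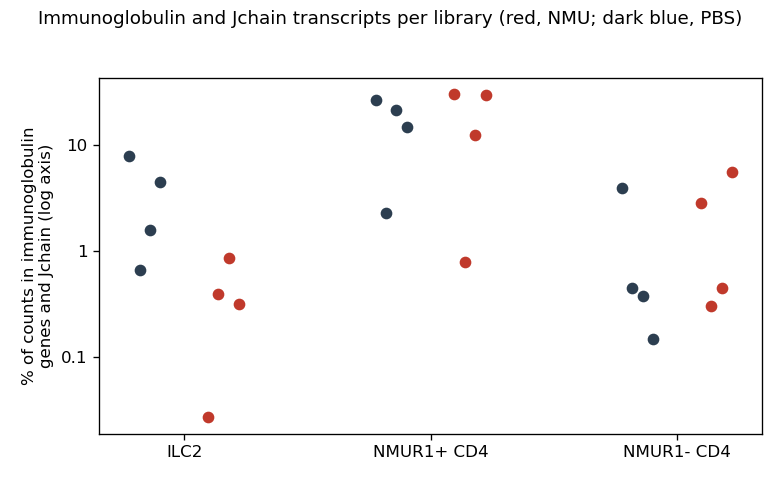
Share of each library's counts in immunoglobulin genes and Jchain (%, log axis), by population, with 1 point per library in red for NMU and dark blue for PBS. NMUR1+ libraries reached 30.4%, and the ILC2 libraries lay between 0.027 and 0.869% with NMU and between 0.666 and 7.94% with PBS.

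NMU was first compared with PBS in colonic ILC2. ILC2 of NMU mice had more RNA of a prohormone convertase and of several surface receptors and ligands, and less of a Notch target, an AP-1 subunit and a heat shock cochaperone. Pcsk1, which cleaves prohormones and proneuropeptides, averaged 234 ± 82.6 CPM with NMU and 28.6 ± 5.90 CPM with PBS (SD, n = 4 each; log2 difference 3.01, SE 0.30, edgeR adjusted p = 0.0017). Ctla4, an inhibitory receptor of lymphocytes, was at 133 ± 76.2 against 25.6 ± 6.47 CPM (log2 2.36, SE 0.37, edgeR adjusted p = 0.0248). The costimulatory receptor OX40 (Tnfrsf4) rose from 14.9 ± 5.52 to 72.3 ± 15.6 CPM and its ligand (Tnfsf4) from 16.9 ± 6.73 to 70.6 ± 12.3 CPM (log2 2.26 and 2.04, SE 0.33 and 0.31, edgeR adjusted p = 0.0187 and 0.0219). Cd83, a surface protein of activated lymphocytes and dendritic cells, rose from 814 ± 358 to 2947 ± 763 CPM (log2 1.84, SE 0.32, edgeR adjusted p = 0.0346). In all of these genes each of the 4 NMU libraries lay above all 4 PBS libraries.

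Other genes rose in ILC2 as well. Rem2, a small GTPase that inhibits voltage-gated calcium channels, was at 86.8 ± 34.6 against 11.6 ± 5.97 CPM, and Serpinb6a, a serine protease inhibitor, at 129 ± 30.8 against 26.4 ± 3.46 CPM. Cxcl3, a chemokine for neutrophils, was at 25.6 ± 7.09 against 4.07 ± 1.72 CPM, and Asf1b, a histone chaperone of replicating cells, at 86.6 ± 32.5 against 20.3 ± 9.97 CPM. Their log2 differences were 2.88, 2.26, 2.63 and 2.07, with edgeR adjusted p from 0.00156 to 0.0456. Epcam, an adhesion protein, was also higher (42.8 ± 12.4 against 11.4 ± 2.61 CPM, log2 1.88, edgeR adjusted p = 0.0308). No other of the 6 tested epithelial markers passed, and the epithelial list had no direction (camera adjusted p = 0.996). Klrg1, an inhibitory receptor on which the ILC2 were also gated, rose from 831 ± 129 to 1489 ± 176 CPM (log2 0.82, SE 0.14, edgeR adjusted p = 0.0300).

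Of the genes that fell, Usp2, a deubiquitinase, had the smallest p-value. It went from 123 ± 13.2 to 39.5 ± 7.95 CPM (log2 -1.66, SE 0.20, edgeR adjusted p = 0.00664). Hes1, a transcription factor induced by Notch, fell from 1843 ± 116 to 776 ± 275 CPM (log2 -1.27, SE 0.22). Junb, a subunit of AP-1, fell from 13612 ± 988 to 8549 ± 863 CPM (log2 -0.69, SE 0.10), the edgeR adjusted p of these 2 genes being 0.0344 and 0.0169. The ceramidase gene Acer2 (log2 -1.82), Rsad1 (-2.05), the polarity gene Pard3 (-2.75) and Plek, a substrate of protein kinase C (-3.28), fell with edgeR adjusted p from 0.0275 to 0.0456. Ly6c2, a surface protein of monocytes and some lymphocytes, and Pfkfb4, a regulator of glycolysis, had 1 count each over the 4 NMU libraries against 710 and 536 counts over the PBS libraries.

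Genes past the test numbered 74 of 11205, 45 higher and 29 lower with NMU, and 30 and 16 of them changed at least 2-fold. The number rested on the mice: it was 45 without mouse 2, 12 without mouse 3, 15 without mouse 4, 12 without mouse 5, 39 without mouse 6, 20 without mouse 7 and 12 without mouse 8. DESeq2 called 472 genes, limma voom 126 and a fit of all 24 libraries 1053. With log2 CPM of Jchain and Lyz2 as covariates, a setting chosen after the data were seen, 5 genes passed (Ighv1-64, Ighv1-80, Irf4, Cd52 and Dusp4, chosen after their values were seen).

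Pcsk1, Serpinb6a and Usp2 passed whichever mouse was left out. Cxcl3, Ly6c2, Rsad1 and Dnaja1 no longer passed without any 1 of the 8 mice (edgeR adjusted p 0.0528 to 0.212), and Acer2 and Rem2 without any but mouse 2 (0.0524 to 0.1285). The same held for Mcm5 without any but mouse 1 (0.0547 to 0.0987), for Cd83 and Pard3 without any but mouse 6 (0.0504 to 0.136) and for Plek without any but mouse 7 (0.0647 to 0.144, with a log2 of -2.65 without mouse 8). Klrg1, Hes1 and Epcam no longer passed without 1 of mice 3 to 8 (0.0547 to 0.125), and Asf1b, Tnfsf4 and Pfkfb4 without 1 of mice 2, 3, 4, 5, 7 and 8 (0.0523 to 0.161). Ctla4 failed without 1 of mice 4 to 8 (0.0547 to 0.0980), Tnfrsf4 without 1 of mice 3 to 6 (0.0531 to 0.0623) and Junb without mouse 3, 4, 5 or 8 (0.0537 to 0.0629). Limma voom did not call Cxcl3 (0.0617), Ly6c2 (0.226), Pfkfb4 (0.0818), Plek (0.321), Pard3 (0.0816) or Rsad1 (0.1001), and the fit of all 24 libraries did not call Klrg1 (0.250) or Junb (0.291). Dnaja1 missed with DESeq2 size factors (0.057) and Cd83 without a filter (0.0545). With the covariates none of the genes above passed, with edgeR adjusted p from 0.0772 for Serpinb6a to 0.444 for Ly6c2, and none of them changed direction in any alternative.

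Among the gene lists, markers of regulatory T cells moved up in ILC2 with NMU. Of 12 tested members 2 rose, Ctla4 and Tnfrsf4, and 5 rose and 1 fell when adjusted over the list alone (camera adjusted p = 5.8e-06; adjusted p = 0.22 with an estimated correlation). Both genes are also induced in other activated lymphocytes, and Foxp3, the factor that defines regulatory T cells, had 12 counts over all 8 ILC2 libraries. Proliferation genes were higher as a list. Of 27, only the replication helicase gene Mcm5 rose over all genes (40.9 ± 4.54 to 105 ± 24.9 CPM, log2 1.34, edgeR adjusted p = 0.0275), and 7 rose adjusted over the list alone (camera adjusted p = 2.06e-09; adjusted p = 0.464 with an estimated correlation). Oxidative phosphorylation (75 genes, 0 past over all genes, 3 up adjusted over the list alone), cytosolic ribosomal proteins (79 genes, 0 and 0) and mitochondrially encoded genes (8 genes, 0 and 0) were shifted up. Their camera adjusted p were 7.3e-09, 0.00397 and 0.0389 (adjusted p = 0.464, 0.823 and 0.603 with an estimated correlation). The ribosomal call ended without mouse 1 (0.643), and with the covariates that list had a median of -0.06. The mitochondrial call ended without mouse 1, 2, 3, 6 or 8 (0.0511 to 0.166) and with the covariates (0.0613).

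Immediate early and activation genes were shifted down. Of 25, only Junb fell over all genes and 7 fell adjusted over the list alone (camera adjusted p = 7.39e-05; adjusted p = 0.464 with an estimated correlation). Heat shock genes were lower as well, with 1 of 12 down over all genes, the cochaperone gene Dnaja1 (913 ± 107 to 514 ± 106 CPM, log2 -0.85, edgeR adjusted p = 0.0470), and 3 down adjusted over the list alone (camera adjusted p = 0.000552; adjusted p = 0.464 with an estimated correlation). Lists of other cell types also moved down with NMU, beside the lower immunoglobulin share of the NMU libraries. They were B and plasma cells (11 genes, 0 past over all genes, 1 up and 5 down adjusted over the list alone, camera adjusted p = 0.000846), macrophages and dendritic cells (16 genes, 0, and 1 down, 0.00742) and fibroblasts (11 genes, 0, and 4 down, 6.66e-06). With an estimated correlation their adjusted p were 0.464, 0.665 and 0.464. The macrophage call ended without mouse 4 (0.064) or 6 (0.0673), and with the covariates its median was 0.07. The B and plasma cell call ended with the covariates (0.179) and with immunoglobulin genes left out (0.388). The lists of ILC2 identity genes (18 tested, 1 up and 1 down, 3 and 3 adjusted over the list alone) and type 2 cytokines (14 tested, 0 past, 5 up and 7 down adjusted over the list alone) had no common direction (camera adjusted p = 0.451 and 0.532).

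The preset cytokine genes did not pass in ILC2. Areg, the gene for the epithelial growth factor amphiregulin (gene 11839, protein coding, chromosome 5, 91139599 to 91148432), averaged 544 ± 169 CPM with NMU and 243 ± 50.6 CPM with PBS, higher in 4 of 4 mice (log2 1.14, SE 0.23, edgeR adjusted p = 0.0679). It passed in 5 of 17 alternatives, whose adjusted p ran from 7.83e-05 with DESeq2 to 0.271. Il5, which sustains eosinophils (gene 16191, protein coding, chromosome 11, 53720794 to 53725103), was at 1647 ± 230 against 1016 ± 225 CPM, also higher in 4 of 4 mice (log2 0.67, SE 0.17, edgeR adjusted p = 0.113). It passed with DESeq2 (0.00337; range over 17 alternatives 0.00337 to 0.661). Csf2, the gene for GM-CSF (gene 12981, protein coding, chromosome 11, 54247270 to 54249899), was at 23.2 ± 8.84 against 8.84 ± 2.68 CPM (log2 1.36, SE 0.43, edgeR adjusted p = 0.208). Il10, an anti-inflammatory cytokine gene (gene 16153, protein coding, chromosome 1, 131019845 to 131024970), was at 81.2 ± 69.1 against 5.58 ± 6.59 CPM (log2 3.85, SE 1.14, edgeR adjusted p = 0.182). It passed in the fit of all 24 libraries (0.0206; range 0.0206 to 0.5). Il13 (gene 16163, protein coding, chromosome 11, 53631323 to 53634702) was at 155 ± 25.2 against 272 ± 165 CPM (log2 -0.84, SE 0.36, edgeR adjusted p = 0.367). Il4 (gene 16189, protein coding, chromosome 11, 53612460 to 53618665) was at 12.47 ± 6.15 against 34.8 ± 17.7 CPM (log2 -1.50, SE 0.47, edgeR adjusted p = 0.201) and passed with DESeq2 (0.0453; range 0.0453 to 0.638). Nmur1 itself was at 239 ± 69.8 against 228 ± 50.8 CPM (log2 0.05, SE 0.23, edgeR adjusted p = 0.960).

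**Figure D2:**
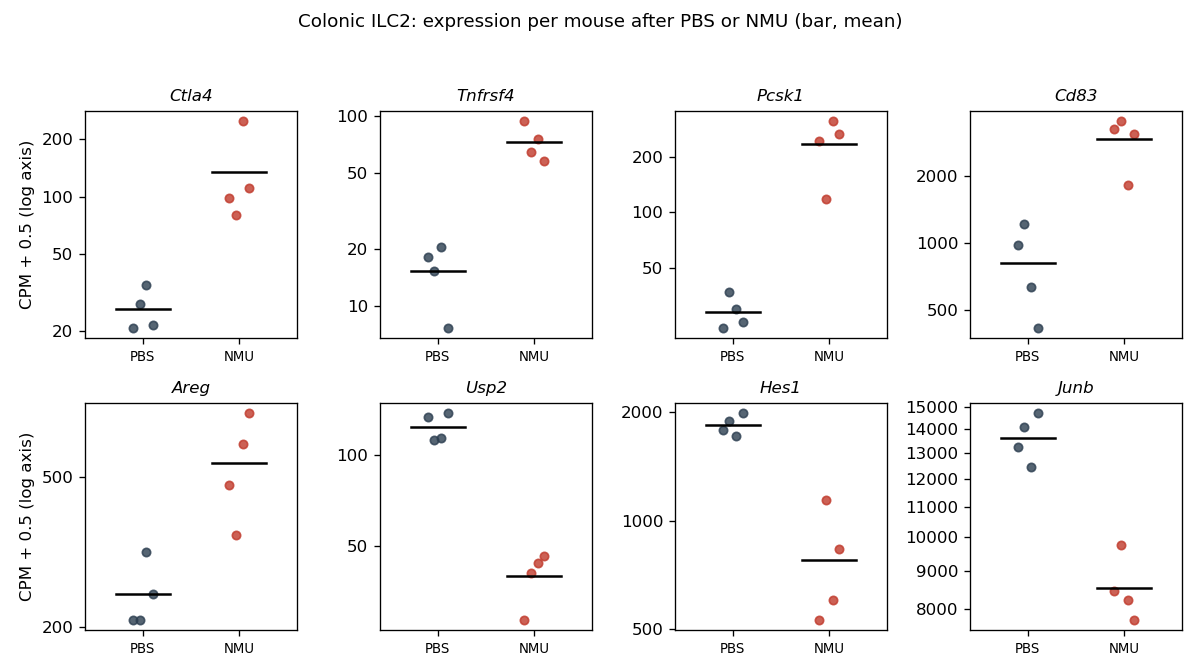
Expression of 8 genes in ILC2 (CPM plus 0.5, log axis) in PBS and NMU mice, with 1 point per mouse and a bar at the mean of 4. Ctla4, Tnfrsf4, Pcsk1 and Cd83 lay higher in all 4 NMU mice than in any PBS mouse, and Usp2, Hes1 and Junb lower. Genes named for the size of their change had to show such a gap. Areg, at 544 against 243 CPM, lay higher in 4 of 4 NMU mice without passing the test (edgeR adjusted p = 0.0679).

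In NMUR1+ CD4 T cells, which express the receptor, no gene passed the edgeR test of NMU against PBS mice. An unadjusted p under 0.05 was found for 307 of 12061 genes, limma voom called 0 and DESeq2 2. The 2 were Agr2, a secretory gene of goblet cells (log2 -5.39, DESeq2 adjusted p = 0.0198), and Mfap5, a microfibril gene of fibroblasts (log2 -5.81, DESeq2 adjusted p = 0.000575), chosen after their values were seen. Without mouse 2, edgeR called 1 gene, the immunoglobulin segment Ighv1-52 (log2 7.79, adjusted p = 0.0395), chosen after its value was seen. The smallest edgeR p-values, all with adjusted p of 1.00, belonged to Adh1, an alcohol and retinol dehydrogenase (4.03 ± 2.45 with NMU against 19.5 ± 8.88 CPM with PBS), Fbxl4 (4.32 ± 1.60 against 13.3 ± 2.92 CPM), Rasgrp3 (6.33 ± 3.51 against 22.1 ± 9.30 CPM), Agr2 (0.634 ± 0.288 against 26.4 ± 30.5 CPM) and Rnf145 (99.5 ± 5.85 against 133 ± 8.67 CPM). Areg was at 156 ± 32.0 with NMU and 123 ± 24.6 CPM with PBS (log2 0.35, SE 0.19) and Il5 at 36.8 ± 33.4 and 20.2 ± 18.9 CPM (0.86, SE 0.91). Il10 was at 413 ± 187 and 409 ± 220 CPM (0.02, SE 0.40) and Nmur1 at 41.2 ± 28.3 and 41.1 ± 23.7 CPM (0.01, SE 0.69), each of these genes with an edgeR adjusted p of 1.00. Il13 and Il4 varied widely between mice (log2 0.36, SE 1.42, and -0.76, SE 1.16; both 1.00), and Csf2 had 19 counts over the NMU and 4 over the PBS libraries. The direction of Nmur1, Il13, Il4 and Il10 turned in some alternatives, with Il13 at -1.09 without mouse 3, Il4 at 0.52 without mouse 7, Il10 at -0.34 without mouse 2 and Nmur1 at -0.45 without mouse 3. Of 33 gene lists, oxidative phosphorylation (76 genes, 0 past over all genes, 0 adjusted over the list alone) was shifted up and fibroblast genes (12 genes, 0 and 0) down (camera adjusted p = 0.0189 and 0.00269; adjusted p = 0.944 for both with an estimated correlation). The first call ended without mouse 2, 3, 7 or 8 (0.103 to 0.289) and the fibroblast call without mouse 6 (0.308).

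In NMUR1- CD4 T cells edgeR again called 0 genes, with 877 of 12103 at an unadjusted p under 0.05. Limma voom called 0, and DESeq2 called 21, 1 higher and 20 lower with NMU. The smallest edgeR p-values, with an adjusted p of 0.577, were those of Scap, a chaperone of sterol-sensing transcription factors (13.2 ± 1.30 with NMU against 27.4 ± 6.68 CPM with PBS), Gga1, Map7d1, Cxcl12 and Rnf40, with log2 differences from -1.72 to -0.95. Areg was at 49.6 ± 40.4 with NMU and 39.5 ± 28.9 CPM with PBS (log2 0.32, SE 0.74), Il10 at 178 ± 111 and 155 ± 47.8 CPM (0.19, SE 0.46) and Nmur1 at 4.64 ± 3.37 and 4.13 ± 1.94 CPM (0.17, SE 0.55). Their edgeR adjusted p were 0.954, 0.958 and 0.970, and their direction turned without mouse 4 (Areg -0.12, Nmur1 -0.21) or mouse 1 (Il10 -0.15). Il5 had 9 counts over the NMU and 17 over the PBS libraries, Il13 17 and 8, Il4 12 and 6 and Csf2 9 and 31, too few to test.

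As lists in NMUR1- cells, oxidative phosphorylation (76 genes, camera adjusted p = 1.27e-07; adjusted p = 0.997 with an estimated correlation), cytosolic ribosomal proteins (78 genes, 0.00316; 0.997), mitochondrially encoded genes (8 genes, 0.0215; 0.944), NK cell genes (11 genes, 0.00316; 0.33) and gamma-delta T cell genes (5 genes, 0.0394; 0.429) were shifted up. Fibroblast genes (12 genes, 1.32e-13; 0.429), NF-kappaB targets (19 genes, 0.0215; 0.89) and tissue repair genes (12 genes, 0.0257; 0.709) were shifted down. No member of these lists passed over all genes, and adjusted over the list alone 1 NK cell gene was up and 2 fibroblast genes were down. Calls ended without mouse 2, 3 or 5 for ribosomal proteins (0.195 to 0.209) and tissue repair (0.074 to 0.236), without mouse 2 or 3 for NF-kappaB targets (0.0733 to 0.156) and without mouse 3 for mitochondrial genes (0.102). The gamma-delta list failed without mouse 1, 4, 6 or 8, with immunoglobulin genes left out and with the covariates (0.078 to 0.19). By camera at the preset correlation, fibroblast genes were thus lower and oxidative phosphorylation higher with NMU in all 3 populations. Ribosomal proteins and mitochondrially encoded genes were called higher in both ILC2 and NMUR1- cells. A cause common to the populations was not tested.

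The NMU effect in ILC2 was then set against that in CD4 T cells. Of the named genes, Ctla4 differed in a way that its own effects explain: its log2 change was 2.36 (SE 0.37) in ILC2, 0.06 (SE 0.18) in NMUR1+ and 0.11 (SE 0.13) in NMUR1- cells. The difference was 2.31 (SE 0.37, edgeR adjusted p = 0.00341) against NMUR1+ and 2.27 (SE 0.37, 0.00375) against NMUR1- cells. Ndrg1, a stress-induced gene, had a log2 change of 2.81 (SE 0.78) in ILC2, -0.30 in NMUR1+ and -0.45 in NMUR1- cells, with differences of 3.13 and 3.26 (edgeR adjusted p = 0.0407 and 0.0349). Tox2, a transcription factor of lymphocytes, differed from NMUR1- cells (log2 3.13, edgeR adjusted p = 0.0382). Gpr174, a lysophosphatidylserine receptor of lymphocytes, differed from NMUR1+ and NMUR1- cells by 4.97 and 5.10 (0.0216 and 0.0175), Hsbp1l1 by 6.23 and 5.94 (0.0296 and 0.0382), and the mitotic kinase gene Nek2 from NMUR1+ cells by 5.93 (0.0395).

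The largest differences in the other direction were in genes with a count of 0 in all 4 NMU ILC2 libraries. NMU ILC2 libraries held counts for 10778 to 12637 genes and PBS ILC2 libraries for 12635 to 13736. Whether the fewer genes detected with NMU account for such zeros was not tested. The folds below cover counting error only. Snx9, a sorting nexin of endocytosis, averaged 6.77 CPM in PBS ILC2, with 4.07 to 12.2 CPM in its 4 libraries, and was at least 104-fold lower with NMU. Its log2 change was -0.11 (SE 0.24) in NMUR1+ and 0.23 (SE 0.39) in NMUR1- cells (edgeR adjusted p of the differences 0.000131 and 6.01e-05). The others, with PBS mean and fold, were the collagenase gene Mmp13 (13.1 CPM, at least 202-fold) and Ltbp4 of the extracellular matrix (12.0 CPM, at least 185-fold). Aldh3b1, an aldehyde dehydrogenase (7.49 CPM, at least 115-fold), and the sialyltransferase gene St8sia6 (5.65 CPM, at least 87.2-fold) followed. To these came 2 genes of myeloid cells, Aoah (4.49 CPM, at least 69.2-fold) and Clec5a (4.30 CPM, at least 66.3-fold). Aldh3b1 and Mmp13 differed from both CD4 populations, Aoah and Ltbp4 from NMUR1+ and St8sia6 and Clec5a from NMUR1- cells, with edgeR adjusted p from 0.0061 to 0.0323.

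In all, 98 genes differed between ILC2 and NMUR1+ cells in their NMU effect (30 with a higher and 68 with a lower log2 change in ILC2) and 72 between ILC2 and NMUR1- cells (21 and 51), of 13509 tested. With the mouse as a replicate block the numbers were 46 and 36. Limma voom called 1 gene (Irf4, chosen after its value was seen) and 9 genes, and DESeq2 516 and 387. Against NMUR1+ cells the number was 30 without mouse 1 or 5, 59 without 3, 46 without 4, 49 without 6, 55 without 7 and 37 without 8. Against NMUR1- cells it was 20 without mouse 1, 42 without 4, 27 without 5 and 34 without 8.

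Ctla4 and Snx9, and Aoah against NMUR1+ cells, passed these tests whichever mouse was left out, with a log2 of 1.72 for Ctla4 against NMUR1+ cells without mouse 3. Limma voom called none of the named genes (adjusted p 0.0524 for Ctla4 against NMUR1- cells to 0.688 for Nek2). Without the 4 libraries above 20% immunoglobulin only Snx9 passed against NMUR1+ cells (the others 0.0655 to 0.297), and Ctla4, Snx9, Mmp13 and Clec5a against NMUR1- cells (the others 0.0622 to 0.0948). Over 19 alternatives the adjusted p of Ctla4 ran from 1.17e-07 to 0.1003 against NMUR1+ and from 2.46e-07 to 0.0524 against NMUR1- cells, and that of Snx9 from 9.88e-11 to 0.492 and from 1.27e-11 to 0.323. With the covariates Ctla4, Snx9, Aoah and Gpr174 still passed (the others 0.0540 to 0.257).

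The calls of the other genes ended without single mice. For Hsbp1l1 these were mice 1, 3, 5, 6, 7 and 8 in both differences (edgeR adjusted p 0.0511 to 0.165), with a log2 of 4.71 without mouse 1 and 7.46 without mouse 6 against NMUR1+ cells, and 4.69, 5.34 and 7.57 without mouse 1, 5 and 6 against NMUR1- cells. For Ndrg1 they were 1, 2, 3, 4, 7 and 8 in both (0.0603 to 0.131; log2 3.85 without mouse 6 against NMUR1- cells), and for Gpr174 3, 4, 5, 7 and 8 in both and 6 against NMUR1+ cells (0.0602 to 0.0977; log2 5.56 without 6). Nek2 failed without 1 of mice 2 to 8 (0.0533 to 0.122; log2 4.66 without 2 and 9.16 without 8) and Tox2 without 1, 2, 3, 4, 5 or 8 (0.0526 to 0.164; log2 3.72 without 7). Mmp13 failed without 1, 3, 4, 5 or 6 against NMUR1+ and without 1 or 5 against NMUR1- cells (0.0517 to 0.0953), and Aldh3b1 without 1, 3, 4, 5 or 8 and without 1, 4, 5, 7 or 8 (0.0511 to 0.0772). Ltbp4 failed without 1, 3, 4, 5, 6 or 8 (0.0511 to 0.122), St8sia6 without 1, 4, 5, 7 or 8 (0.0829 to 0.110) and Clec5a without 1 or 5 (0.0508 to 0.0585). With the mouse as a replicate block the calls of Hsbp1l1, Gpr174, Ndrg1, Mmp13, Ltbp4, Nek2, St8sia6 and Clec5a ended too (0.0516 to 0.107). The same held for Ndrg1, Nek2 and Tox2 without a filter (0.0548 to 0.0649), and for Hsbp1l1, Ndrg1, Ltbp4, St8sia6 and Tox2 without the ILC2 library of mouse 1 alone (0.0519 to 0.0804).

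None of the preset cytokine genes, nor Nmur1, passed the test of a different NMU effect in ILC2. For Areg the difference was 0.81 (SE 0.70, edgeR adjusted p = 0.700) against NMUR1+ and 0.83 (SE 0.70, 0.768) against NMUR1- cells, and for Il10 3.84 (SE 1.25, 0.165) and 3.66 (SE 1.24, 0.228). Between the CD4 populations edgeR found 0 genes with a different NMU effect, 157 with an unadjusted p under 0.05, and limma voom 0. DESeq2 called 4 there, Glp2r, Ccdc40, Cdkl4 and Arhgef17, and the replicate block 1, Igkv14-130 (log2 10.72, edgeR adjusted p = 0.0101), all chosen after their values were seen. The smallest p-values were those of Apaf1, Map3k1, Atxn1, Lrrc8a and Ttc7 (log2 0.69 to 1.34, edgeR adjusted p = 1.00). Of the 74 genes changed in ILC2, 20 also passed the test of the difference against NMUR1+ and 21 that against NMUR1- cells, but these tests use the same ILC2 libraries and are not independent of the first.

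As lists, regulatory T cell markers (16 genes, 2 up and 1 down over all genes, 4 up and 2 down adjusted over the list alone), proliferation (27 genes, 0 and 0) and oxidative phosphorylation (76 genes, 0 and 0) had higher NMU effects in ILC2 than in NMUR1+ cells (camera adjusted p = 0.016, 2.99e-08 and 0.000358). Heat shock (12 genes, 0, and 2 down adjusted over the list alone), B and plasma cells (15, 0, and 1 down), macrophages and dendritic cells (19, 1 down, and 3 down) and fibroblasts (13, 0, and 1 down) had lower effects (0.0205, 0.0338, 0.00154 and 0.000716). The same 7 lists were called against NMUR1- cells, with camera adjusted p from 9.22e-08 to 0.0273. Adjusted over the list alone, 3 heat shock, 2 B and plasma cell, 2 macrophage and 4 fibroblast genes were lower there, none of them past over all genes. With an estimated correlation none of the 14 calls held (adjusted p = 0.868 for all 7 against NMUR1+ cells, and adjusted p from 0.662 to 0.947 against NMUR1- cells). For the regulatory T cell markers the medians were 0.43 and 0.36 and the means -0.12 and -0.11, and the calls ended without mouse 3 (0.104 and 0.123). Between the CD4 populations, endothelial genes (7 genes, 0 past over all genes, 1 up adjusted over the list alone) had a higher effect in NMUR1+ cells (camera adjusted p = 0.000429; adjusted p = 0.312 with an estimated correlation).

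Other calls among these 14 ended as follows. Oxidative phosphorylation failed without mouse 1 against NMUR1+ (0.0664) and without mouse 1, 4, 7 or 8 against NMUR1- cells (0.0972 to 0.787), and heat shock without 1, 2 or 6 (0.0632 to 0.0835) and without 1, 2, 4, 6 or 8 (0.0542 to 0.175). B and plasma cells failed without 1, 3, 5, 6 or 8 against NMUR1+ (0.0617 to 0.121) and without 8 against NMUR1- cells (0.0684), and macrophages without 6 (0.161) and without 4 or 6 (0.0602 to 0.0788). Fibroblasts failed against NMUR1- cells without 2, 4 or 6 (0.0602 to 0.299). With the covariates, oxidative phosphorylation, heat shock, B and plasma cells and macrophages no longer passed in either difference, nor fibroblasts against NMUR1- cells (0.0824 to 0.795). Without the 4 libraries above 20% immunoglobulin, oxidative phosphorylation, heat shock and B and plasma cells failed against NMUR1+ cells (0.0965 to 0.186), and B and plasma cells in both differences with immunoglobulin genes left out (0.394 and 0.479). With a replicate block, ribosomal proteins also passed against NMUR1+ cells (camera adjusted p = 0.035).

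NMUR1+ were compared with NMUR1- CD4 T cells of the same mice, in a fit not paired by mouse. The NMUR1+ libraries had more RNA of type 2 genes. For Il5, Il13, Hes1, Calca and Il17rb, RNA of ILC2 was not excluded. Gata3, the master factor of type 2 lymphocytes (gene 14462, protein coding, chromosome 2, 9857078 to 9887953), was at 1533 ± 261 against 498 ± 132 CPM (SD, n = 8 each; log2 1.63, SE 0.15, edgeR adjusted p = 7.2e-07). Il1rl1, which encodes the IL-33 receptor (gene 17082, protein coding, chromosome 1, 40404864 to 40465418), was at 265 ± 88.9 against 56.1 ± 17.2 CPM (log2 2.24, SE 0.22, 1.61e-06). Klrg1 (gene 50928, protein coding, chromosome 6, 122270596 to 122282833) was at 709 ± 229 against 111 ± 62.6 CPM (log2 2.68, SE 0.32, edgeR adjusted p = 2.49e-05). Il5 was at 28.5 ± 26.7 against 0.189 ± 0.286 CPM (log2 7.01, SE 0.78, 1.7e-05), and Il13 at 13.7 ± 17.4 against 0.236 ± 0.220 CPM (log2 5.98, SE 0.98, 0.000677). Areg was at 139 ± 31.8 against 44.6 ± 32.9 CPM (log2 1.65, SE 0.36, edgeR adjusted p = 0.00545). Each of these 6 genes but Il13 was higher in all 8 NMUR1+ libraries than in any NMUR1- library, and Il13 in 7 of 8. Nmur1 itself was higher (log2 3.24, SE 0.45, edgeR adjusted p = 0.000118), also above every NMUR1- library in 7 of 8. The exception was mouse 1, with 6.09 CPM in NMUR1+ and 7.22 CPM in NMUR1- cells.

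Hes1 (46.3 ± 17.3 against 10.2 ± 6.08 CPM), the IL-25 receptor gene Il17rb (45.4 ± 48.1 against 1.39 ± 0.878 CPM), Calca, the gene for the neuropeptide CGRP (21.1 ± 18.6 against 1.76 ± 1.01 CPM), and the chemokine gene Ccl1 (10.03 ± 8.17 against 1.02 ± 0.442 CPM) were also higher in NMUR1+ cells, with edgeR adjusted p from 2.94e-06 to 0.000179. Il21, a helper cytokine for B cells, was lower (1.86 ± 1.64 against 20.6 ± 10.1 CPM, log2 -3.73, SE 0.62), as was Tcf7, a factor of naive and memory T cells (37.1 ± 16.3 against 196 ± 39.3 CPM, log2 -2.40, SE 0.24). So were its relative Lef1 (log2 -1.51), the homing receptor gene Ccr7 (-0.99), the death ligand gene Fasl (-1.48) and the IL-12 receptor gene Il12rb2 (-1.77), these 6 genes with edgeR adjusted p from 2.33e-06 to 0.00941. Cd3e (gene 12501, protein coding, chromosome 9, 44998735 to 45009663) and Cd4 (gene 12504, protein coding, chromosome 6, 124864693 to 124888247) did not pass. Their log2 differences were -0.11 and -0.23 (SE 0.41 and 0.49; edgeR adjusted p = 0.938 and 0.874). Foxp3 (gene 20371, protein coding, chromosome X, 7579676 to 7595243) averaged 250 ± 55.8 in NMUR1+ and 145 ± 48.9 CPM in NMUR1- cells without passing (log2 0.79, SE 0.36, edgeR adjusted p = 0.209). It passed in 3 of 21 alternatives, whose adjusted p ran from 0.00339 with limma voom to 0.879.

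Of the other genes with the largest differences, Ighg1, Igha and Igkc of immunoglobulins and Chil3, Gpr141 and Hp of myeloid cells were higher in NMUR1+ cells (log2 3.79 to 5.16, edgeR adjusted p 0.0054 to 0.0316). Igha averaged 64872 ± 48676 against 4796 ± 5936 CPM. Gzmk, Myb, Cd160, St8sia1, Sidt1 and Tnfrsf26 were lower (log2 -2.36 to -1.91, edgeR adjusted p 4.95e-05 to 0.0423).

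By list, ILC2 identity genes (18 tested, 12 up over all genes, 14 up adjusted over the list alone; camera adjusted p = 9.29e-26), Th2 genes (11, 9 up and 9 up; 3.24e-18) and type 2 cytokines (14, 7 up and 7 up; 1.24e-09) were higher in NMUR1+ cells, with none down. All 3 held with an estimated correlation (adjusted p = 1.83e-06, 2.31e-05 and 0.00385). Regulatory T cell genes (16 tested, 5 up and 5 up adjusted over the list alone; camera adjusted p = 2.16e-06, adjusted p = 0.0314 with an estimated correlation) were led by the costimulatory receptor gene Tnfrsf9 (1799 ± 484 against 805 ± 214 CPM, log2 1.17), Tnfrsf18 (0.67) and Il2ra (0.65), genes that other activated T cells also express. Immediate early genes (25 tested, 13 up and 15 up adjusted over the list alone; 1.32e-13, adjusted p = 0.0451 with an estimated correlation) and NF-kappaB targets (19, 10 up and 12 up; 5.12e-10, adjusted p = 0.0314 with an estimated correlation) were higher too. They included Cxcl2, a neutrophil chemokine (59.7 ± 14.2 against 11.3 ± 3.33 CPM, log2 2.43, edgeR adjusted p = 5.77e-08), the inhibitor Nfkbia (log2 0.74), Ier3 (2.49) and Zfp36 (1.27). Naive and central memory genes (12 tested, 6 down and 6 down adjusted over the list alone; 3.43e-10, adjusted p = 0.00132 with an estimated correlation) and Th1 genes (12, 5 down, and 1 up and 8 down adjusted over the list alone; 0.00024, adjusted p = 0.00519 with an estimated correlation) were lower.

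Markers of other cells were higher beside these lists, as was the immunoglobulin share. Class II antigen presentation genes (7 of 7 up, 7 adjusted over the list alone, camera adjusted p = 8.63e-19) included H2-Ab1 at 3630 ± 1273 against 815 ± 299 CPM. Macrophage and dendritic cell genes (6 of 19 up, 13 adjusted over the list alone, 7.83e-13) included Cd14 (log2 2.61), Ctss (1.33) and Cst3 (1.08). Both held with an estimated correlation (adjusted p = 0.00519 and 0.0442). B and plasma cell genes (6 of 15 up, 8 adjusted over the list alone, 2.86e-06), the unfolded protein response (7 of 16 up, 8 adjusted over the list alone, 0.000427), tissue residency (3 of 11 up, 5, 0.00238) and the interferon response (2 of 22 up, 5, 0.00875) were higher. So, by camera, were neutrophil genes (1 of 8 up, 1, 0.0169; median log2 1.003, but -0.348 to -0.159 without mouse 1, 2, 4, 5, 6 or 7, where the call ended) and neuropeptide receptors (2 of 9 up, 2, 0.0362; Nmur1 among them). None of these 6 held with an estimated correlation (adjusted p = 0.0884, 0.282, 0.0884, 0.46, 0.414 and 0.0884). Lower were alpha-beta CD4 T cell identity (3 of 18 down, 4 adjusted over the list alone, 0.0169), proliferation (5 of 27, 7, 4.37e-05), ribosomal proteins (11 of 79, 24, 1.61e-07), oxidative phosphorylation (0 of 76, 0, 0.0147), endothelial genes (0 of 7, 2, 0.0336) and mitochondrially encoded genes (1 of 8, 5, 0.0336). With an estimated correlation these gave adjusted p = 0.169, 0.46, 0.487, 0.692, 0.282 and 0.46.

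In all, 1123 of 13509 genes differed between the CD4 populations, 741 higher and 382 lower in NMUR1+ cells. The number was 713 without mouse 3, 609 without mouse 7, 676 without mouse 8, 393 without the 4 libraries above 20% immunoglobulin and 239 with Jchain and Lyz2 as covariates. It was 315 in PBS mice alone, 110 in NMU mice alone, 2605 with limma voom and 2104 in a fit of the 16 libraries. Gata3, Klrg1, Il1rl1, Il5, Hes1, Tcf7, Cxcl2, Nfkbia, Ier3, Zfp36, H2-Ab1, Ctss and Cst3 passed in all 21 alternatives. Il5 had a log2 of 6.42 without mouse 3, 8.09 without mouse 4 and 8.13 without mouse 8. Il13 was at 5.25 without mouse 3, 7.09 without mouse 7 and 4.23 with limma voom, Il17rb at 4.29 without mouse 3 and 4.10 with limma voom, and Il21 at -4.73 without mouse 5.

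In NMU mice alone (n = 4) Nmur1 (edgeR adjusted p = 0.0734), Il13 (0.0708), Il17rb (0.0644), Calca (0.0721), Ccl1 (0.0596) and Tnfrsf9 (0.0734) failed. So did Tnfrsf18 (0.147), Il2ra (0.0758), Tnfrsf26 (0.0546), Areg (0.244), Lef1 (0.0644), Ccr7 (0.0684), Fasl (0.154), St8sia1 (0.0832) and Cd14 (0.113). In PBS mice alone Il2ra (0.129), Il21 (0.0636), Ccr7 (0.0551), Fasl (0.131), Il12rb2 (0.211), Cd160 (0.130) and St8sia1 (0.0550) failed. With the covariates Areg (0.0776, log2 1.30), Il21 (0.108, -4.03), Lef1 (0.0609, -0.91), Fasl (0.0803, -1.615), Il12rb2 (0.311, -1.54) and Cd14 (0.0965, 2.24) failed. Without the 4 libraries Areg (0.0860), Fasl (0.103) and Il12rb2 (0.0857) did. Over 21 alternatives Areg gave 7.18e-05 to 0.244 and Nmur1 5.27e-12 to 0.0734.

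Calls of several of these genes ended in the alternatives. Igha no longer passed without mouse 1, 3, 4, 6, 7 or 8 (edgeR adjusted p 0.0569 to 0.119; log2 4.82 without mouse 5), and Igkc without 1, 2, 3, 4, 6, 7 or 8 (0.0515 to 0.120; log2 4.54 without mouse 5). Hp failed without 1, 2 or 7 (0.0574 to 0.0820), Gpr141 without 7 (0.0596) and Sidt1 without 8 (0.0676). Myb failed without 1, 2, 3, 4, 7 or 8 (0.0577 to 0.112) and with the mouse as a replicate block (0.0654). Ighg1 had a log2 of 6.43 without mouse 4 and Chil3 of 3.64 without mouse 3. With Jchain and Lyz2 as covariates the log2 of Igha was 0.70, that of Igkc 0.66, that of Gpr141 1.81 and that of H2-Ab1 1.48, and Ighg1, Chil3, Hp, Gzmk, Myb and Sidt1 did not pass (0.114 to 0.402). Of these lost calls, Chil3 (5.08), Hp (4.77), Gzmk (-3.25) and Myb (-3.10) had a larger log2 in size than in the main fit. Ighg1 (3.36) had a smaller one, and Sidt1 was at -2.04. Igha, Igkc, Gpr141, Gzmk, Myb and Sidt1 passed in neither treatment alone (0.0556 to 0.475), Chil3 and Hp not in PBS mice (0.181 and 0.325) and Ighg1 not in NMU mice (0.593). Without the 4 libraries above 20% immunoglobulin all of these but Chil3 failed (0.0586 to 0.388).

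Among the lists, neuropeptide receptors failed without mouse 2, 3, 6, 7 or 8 (camera adjusted p 0.093 to 0.166), neutrophils without 1, 2, 4, 5, 6 or 7 (0.0582 to 0.0978), endothelial genes without 1, 6 or 8 (0.0605 to 0.0744) and mitochondrial genes without 3, 4, 6 or 8 (0.0503 to 0.0724). The interferon response (0.0534) and oxidative phosphorylation (0.114) failed without mouse 8. With the covariates, neuropeptide receptors (0.0637), ribosomal proteins (0.0535), macrophages (0.0944), neutrophils (0.0598) and endothelial cells (0.151) no longer passed and oxidative phosphorylation turned (median 0.01). CD4 T cell identity and neuropeptide receptors (both 0.0817) and oxidative phosphorylation (0.412) failed without the 4 libraries. With the mouse as a replicate block the heat shock list passed as well (0.035).

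**Figure D3:**
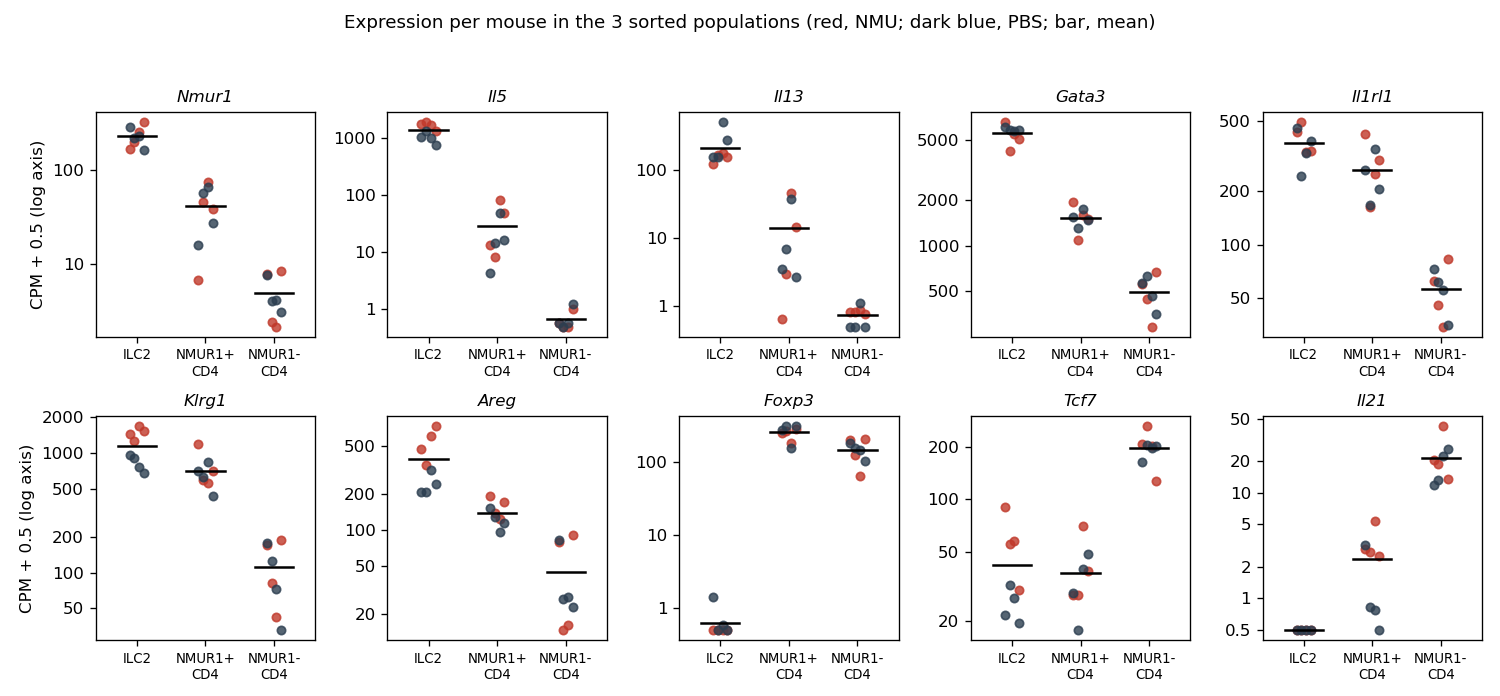
Expression of 10 genes (CPM plus 0.5, log axis) in ILC2, NMUR1+ and NMUR1- CD4 T cells, with 1 point per library, red for NMU and dark blue for PBS. Nmur1 averaged 233, 41.2 and 4.38 CPM and Il5 1331, 28.5 and 0.189 CPM in the 3 populations, Foxp3 was found in the CD4 populations, and Tcf7 and Il21 were highest in NMUR1- cells.

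ILC2 were then compared with each CD4 population. They had the highest levels of several type 2 genes. Gata3 averaged 5614 ± 697 CPM in ILC2 (SD, n = 8; log2 1.88, SE 0.15, against NMUR1+ and 3.51, SE 0.16, against NMUR1- cells; edgeR adjusted p = 1.43e-09 and 1.28e-13). Il5 was at 1331 ± 397 CPM, Il13 at 214 ± 126 CPM, Areg at 394 ± 198 CPM and Nmur1 at 233 ± 56.9 CPM. Each was higher in all 8 ILC2 libraries than in any library of either CD4 population, with edgeR adjusted p from 2.48e-09 to 0.00368, though Areg missed the threshold against NMUR1+ cells in PBS mice alone (0.0523; range over 22 alternatives 4.09e-06 to 0.0523). Klrg1 (1160 ± 380 CPM) and Il1rl1 (376 ± 81.0 CPM) were higher than in NMUR1- cells (log2 3.34 and 2.75, SE 0.33 and 0.22, edgeR adjusted p = 8.86e-08 and 1.14e-09). Against NMUR1+ cells they did not pass (log2 0.66 and 0.51, edgeR adjusted p = 0.0945 and 0.0572) unless the mouse was a replicate block (0.034 and 0.029). The T cell genes Cd3e (5.69 ± 4.04 CPM) and Cd4 (5.81 ± 4.82 CPM) were low in ILC2 against 855 and 623 CPM in NMUR1+ and 927 and 734 CPM in NMUR1- cells, and Foxp3 had 12 counts in ILC2 against 23541 and 16434.

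Genes found mainly in ILC2 included Mycn, a transcription factor of the Myc family (28.8 ± 16.8 CPM against 0 counts in NMUR1+ cells, at least 893-fold), the secretory GTPase gene Rab27b (121 ± 55.0 CPM), the growth factor gene Bmp2 (46.8 ± 21.1 CPM), Igsf5 (245 ± 55.0 CPM), the retinoid receptor gene Rxrg (97.4 ± 36.9 CPM), Fam184b and Cntn1, the last not past in NMU mice alone (edgeR adjusted p = 0.0510). Stab2, Rgs18 and the melanocortin receptor gene Mc5r were among the genes with the largest differences from NMUR1- cells, in which they had 3, 17 and 8 counts over 8 libraries. Kit, a receptor of progenitor and mast cells (427 ± 70.1 CPM), and Ret, a receptor of neurotrophic factors (144 ± 62.4 CPM), were also higher in ILC2 than in either CD4 population.

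Genes found mainly in CD4 T cells included Cd5 and Sh2d1a, an adaptor of T cell signaling (0 counts in ILC2, at least 1622-fold and 3249-fold lower than in NMUR1+ and NMUR1- cells). The chemokine gene Ccl20 (0 counts, at least 473-fold and 605-fold) and its receptor gene Ccr6, Il21 (0 counts, at least 59.0-fold and 651-fold) and Atp6v0d2 (0 counts, at least 528-fold and 497-fold) belonged to them too. So did Ky and Frmd5 (0 counts, at least 1022-fold and 932-fold lower than in NMUR1+ cells) and Galnt9 (0 counts, at least 411-fold lower than in NMUR1- cells). The myeloid gene Chil3 had 10 counts in ILC2 against 82.4 ± 84.9 CPM in NMUR1+ cells, a difference that limma voom did not call (adjusted p = 0.0504).

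ILC2 identity genes were higher in ILC2 (13 up and 2 down of 18 against NMUR1+, 15 and 2 against NMUR1- cells; 15 and 2 in both adjusted over the list alone). They were led by Hilpda (log2 2.80 and 3.76) and Hes1 (4.73 and 7.02), while Icos, a costimulatory receptor gene, was lower (-0.99 against NMUR1- cells). Type 2 cytokines (9 up and 2 down of 14, and 11 and 2; 9 and 2, and 12 and 2 adjusted over the list alone) and Th2 genes (7 and 2 of 11, and 8 and 1; 8 and 2, and 10 and 1 adjusted over the list alone) were higher too. Immediate early genes (21 and 1 of 25, and 22 and 0; the same adjusted over the list alone), neuropeptide receptors (6 and 1 of 9 in both; 6 and 3, and 6 and 1 adjusted over the list alone) and gamma-delta T cell genes (3 and 1 of 6 in both, also adjusted over the list alone) followed. The last included Trgc4 (285 ± 91.1 CPM), Trgc1 (238 ± 80.5 CPM) and Trdv4 (195 ± 24.4 CPM), segments of the gamma and delta receptor loci, and the neuropeptide receptors included Ramp1 (log2 2.41 and 2.81) and Ramp3 (1.54 and 1.49), subunits of the CGRP receptor family. For these 6 lists camera adjusted p ran from 1.3e-31 to 0.00204, and all calls held with an estimated correlation (adjusted p from 1.91e-07 to 0.027). Il10, of the cytokine list, was lower in ILC2 (43.4 ± 60.8 against 411 ± 189 and 166 ± 79.9 CPM), but not in NMU mice alone (edgeR adjusted p = 0.0517 and 0.326).

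Alpha-beta CD4 T cell identity genes were lower in ILC2, 16 of 18 against each population with 1 up. Adjusted over the list alone, 2 were up and 16 down, and 1 and 16. Regulatory T cell genes (2 up and 13 down of 16, and 2 and 12; the same adjusted over the list alone) were lower as well, among them Ctla4 (79.5 ± 76.3 against 1999 ± 400 and 1532 ± 188 CPM) and Tnfrsf4 (43.6 ± 32.5 against 2735 ± 457 and 1848 ± 311 CPM). So were Th1 genes (2 and 8 of 12, and 0 and 9; the same adjusted over the list alone) and, against NMUR1- cells, naive and central memory genes (2 and 9 of 12, also adjusted over the list alone). These calls held with an estimated correlation (adjusted p from 5.87e-06 to 0.0473).

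The other calls were lost with an estimated correlation. Against NMUR1+ cells (adjusted p from 0.133 to 0.542 with an estimated correlation) these were proliferation (0 up and 22 down of 27, 0 and 23 adjusted over the list alone), B and plasma cells (0 and 14 of 15, also adjusted over the list alone), macrophages and dendritic cells (1 and 16 of 19, 1 and 18), class II genes (0 and 7 of 7, 0 and 7) and interferon response (0 and 12 of 22, 0 and 13). To these came Th17 genes (4 and 9 of 13, 4 and 9), CD8 T cell genes (0 and 3 of 4, 0 and 3), ribosomal proteins (54 and 2 of 79, 58 and 2) and NF-kappaB targets (9 and 6 of 19, 9 and 6), the last called up with a median log2 of 0.35 and a mean of -0.06. The Th17 list failed with the mouse as a replicate block (camera adjusted p = 0.0559), without mouse 1, 3 or 4 (0.0515 to 0.0577) and without the 4 libraries (0.0614), and NF-kappaB targets without 1, 2 or 6 (0.0565 to 0.166). With the covariates Th17 genes, macrophages, class II genes and CD8 T cell genes did not pass (0.0939 to 0.894). Against NMUR1- cells the lost calls (adjusted p from 0.0751 to 0.838 with an estimated correlation) were proliferation (0 and 27 of 27, also adjusted over the list alone), oxidative phosphorylation (2 and 46 of 76, 2 and 48), ribosomal proteins (28 and 1 of 79, 28 and 1), NF-kappaB targets (11 and 3 of 19, 12 and 3) and CD8 T cell genes (0 and 4 of 4, 0 and 4). Oxidative phosphorylation also failed without mouse 2 or 8 (0.0509 to 0.0539), and with a replicate block the lists of tissue residency, tissue repair and heat shock passed as well.

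Over all genes, 5218 of 13509 differed between ILC2 and NMUR1+ cells, 2043 higher and 3175 lower in ILC2, and 5471 between ILC2 and NMUR1- cells, 2219 higher and 3252 lower. In NMU mice alone the numbers were 2423 and 2836, and with Jchain and Lyz2 as covariates 2310 genes differed from NMUR1+ cells.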

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

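The tests on batch or handling, CD4 T cell RNA, ILC2 RNA, Jchain and Lyz2 as covariates and clock genes were chosen after the results were seen. The splits of the libraries and the test on plasma cell and macrophage RNA in PBS ILC2 were set before.

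The NMU effect differed between populations by a test of the difference itself in 98 genes for ILC2 against NMUR1+ cells and in 72 genes for ILC2 against NMUR1- cells. Of 35 splits of the mice into 4 and 4, 1 called as many genes in each case, the real one, and the highest other called 19 and 13. That is the smallest share that 35 splits can give, so it argues against chance without excluding it. The named genes, with the log2 difference against NMUR1+ cells, were Hsbp1l1 (6.234), Nek2 (5.933), Gpr174 (4.974), Ndrg1 (3.128), Ctla4 (2.315), Mmp13 (-10.14), Aldh3b1 (-10.01), Ltbp4 (-9.656), Aoah (-9.65) and Snx9 (-9.31). Against NMUR1- cells they were Hsbp1l1 (5.942), Gpr174 (5.102), Ndrg1 (3.264), Tox2 (3.131), Ctla4 (2.267), Mmp13 (-11.33), St8sia6 (-10.06), Aldh3b1 (-9.685), Snx9 (-9.654) and Clec5a (-9.548). Values beyond -9 belong to genes with 0 counts in NMU ILC2 and are fitted, not measured, sizes.

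In 11 of 113 groups of 4 libraries the highest library lay further from the nearest other than Dixon's critical value for 4 values allows, where 5.65 would be expected by chance. Chance marks about 1 in 20 groups. In NMUR1- cells of PBS mice these were the total counts of mouse 8 (17.85 M, nearest 12.64 M, with M for mega), the immunoglobulin share of mouse 5 (3.95%, nearest 0.448%) and the mitochondrial share of mouse 6 (0.722%, nearest 0.624%). In the same cells they were Areg in mouse 5 (82.78 CPM, nearest 27.01), Il5 in mouse 8 (0.7461 CPM, nearest 0.0761) and Il13 in mouse 7 (0.6086 CPM, nearest 0). In NMUR1- cells of NMU mice Il5 stood apart in mouse 4 (0.5333 CPM, nearest 0.0802). In NMUR1+ cells they were Il13 in PBS mouse 7 (36.57 CPM, nearest 6.323) and Il4 in NMU mouse 3 (6.607 CPM, nearest 0.6446). In ILC2 of PBS mouse 5 they were the share of the most abundant gene (2.553%, nearest 1.514%) and Foxp3 (0.9137 CPM, nearest 0.0921).

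The 74 genes past in ILC2 were weighed first. Of 35 splits of the 8 libraries into 4 and 4, only the real one called as many, the highest other 0. This argues against chance, which 35 splits are too few to exclude. Signed by their direction in ILC2, these genes had a mean effect of 1.16 (SE 0.0699) in ILC2. In libraries of the same mice it was 0.1046 (SE 0.0849, 52 of 73 of the same sign) in NMUR1- and 0.156 (SE 0.0711, 59 of 73) in NMUR1+ cells. The CD4 means were small, but the genes were chosen and signed on the ILC2 libraries. Their ILC2 mean is raised by that choice, so no bound can be taken from it. By the library codes, batch or handling, in all libraries of a mouse or in ILC2 alone, and NMU cannot be told apart. Of the 29 genes that fell, 2 had a higher mean in NMUR1+ than in PBS ILC2 libraries. As a set, this argues against RNA of plasma cells and macrophages as the source of their fall. PBS ILC2 libraries did hold such RNA, with 0.666 to 7.94% of counts in immunoglobulin genes and Jchain. The test covers only genes that passed, and RNA of fibroblasts was not tested. Of the 45 genes that rose, all but 2, Ctla4 and Tnfrsf4, rose by more than the largest T cell share (6.61%, from Cd3g) supplies. This argues against RNA of CD4 T cells for the other 43. Ctla4 and Tnfrsf4 need T cell shares higher by 5.394 and 2.098% with NMU, and although Cd4 gave 2.148% in 1 NMU library, so that a first bound on single libraries left this open, the NMU minus PBS differences were -0.4557 (SE 0.3093) by Cd3e, -0.1831 (SE 0.1583) by Trac, -0.0491 (SE 0.5912) by Cd4 and -0.1731 (SE 0.1527) by Foxp3, which argues against RNA of CD4 T cells here too, while Cd3g (1.612, SE 2.78) decides nothing. With the covariates 5 genes passed, and 4 residual degrees of freedom were left. Median log2 (median gene SE) was 1.264 (0.1852), then 1.268 (0.2337), for the genes that rose. It was -1.047 (0.1695), then -1.052 (0.2354), for those that fell. Over all genes the log2 values correlated with those of the main fit at 0.547. Jchain was at 6.88 to 973 CPM in NMU and 1473 to 15220 CPM in PBS ILC2 libraries. Because these ranges do not overlap, the covariate fit cannot separate such RNA from treatment.

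The genes higher in NMUR1+ than in NMUR1- CD4 T cells were weighed next. ILC2 shares of NMUR1+ libraries by 20 ILC2-restricted genes ran from 0.291 to 11.74%, upper quartile 3.47%. Gata3 (20.2%) and Klrg1 (57.0%) need more, which argues against RNA of ILC2 for them. Of 16 ILC2 identity and Th2 members, 3.47% supplies 2, Arg1 and Hes1 (2.779%), and 11.74% was not tried. For Arg1, Hes1, Il5 (2.128%), Il13 (6.32%), Calca (5.53%) and Il17rb (7.40%), ILC2 RNA and T cell expression cannot be told apart. RNA of plasma cells and macrophages is argued against for 18 ILC2 identity and Th2 members. With Jchain and Lyz2 as covariates, 18 stayed higher and 12 past. The median log2 went from 2.26 to 1.867 (median gene SE 0.295 and 0.327). For 17 B and plasma cell, macrophage and class II members, covariate genes left out, it went from 2.03 to 1.079 (0.334 and 0.307). The bound was 1.017, and 8 still passed. No SE of a median was computed. For these 17, RNA of other cells and expression in NMUR1+ cells cannot be told apart.

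Clock genes in ILC2 were weighed last, after Usp2 (log2 -1.66 with NMU, edgeR adjusted p = 0.00664) and Nr1d2 (log2 -0.9964, edgeR adjusted p = 0.0195), both driven by the circadian clock, were seen among the genes that fell. A different time of day of dissection for the 2 treatments would move the clock genes of all cells of a mouse. Signed by their direction in ILC2, 16 clock genes had a mean NMU effect of 0.0783 (SE 0.156) in NMUR1+ and 0.1686 (SE 0.136) in NMUR1- cells. The signing makes the ILC2 mean positive whatever the data, so no bound can be taken from it, and a difference in time of day and a change in ILC2 cannot be told apart.

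For the other comparisons, edgeR gave 0 genes for NMU against PBS in NMUR1+ and in NMUR1- cells and 0 for the difference of the NMU effect between them. A count of 0 is reached by 35 of 35 splits whatever the data, so the splits decide nothing there. The highest other splits called 13, 1401 and 0 genes, and the 1401, with mice 1, 4, 5 and 6 against the rest, point to a structure of the NMUR1- libraries other than treatment. The population comparisons were split in fits of their 16 libraries. The real labels gave 2121 genes for NMUR1+ against NMUR1- cells (1 of 50 splits of the libraries, highest other 1), 3582 for ILC2 against NMUR1+ (1 of 50, highest other 830) and 4422 for ILC2 against NMUR1- cells (1 of 50, highest other 1). Exchanges of the populations within mice reached the real number in 1 of 40 each, with 442, 1 and 2005 genes in the highest other, the 442 and 2005 from the exchange of mouse 6 or mouse 4 alone. For all 3 this argues against chance, which 50 or 40 splits are too few to exclude.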

How the results depend on the processing

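The covariates, the omission of immunoglobulin genes, of libraries over 20% immunoglobulin and of the ILC2 library of mouse 1 were added after seeing the data. The other alternatives were planned.

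Over all alternatives, calls of named genes stayed 8299 times, were lost 873 times and reversed 4 times. Genes that had not passed kept direction and side 941 times, passed 32 times and turned 63 times. List calls stayed 1095 times, were lost 211 times and reversed 6 times, and counts of genes stayed within 1.5 times 136 times and moved 52 times. None of the 74 ILC2 genes changed sign. At this depth and with 4 mice per group, edgeR recovered 14.1% of 2-fold and 53.2% of 4-fold changes on simulated counts for NMU in ILC2, and whether depth, the number of mice or their spread sets this was not tested. The cause was not tested for the changed results, and the values given above for the covariates in ILC2 do not decide it there.

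Counts of genes for NMU in ILC2 (74) were 472 with DESeq2, 126 with limma voom, 1053 with all 24 libraries in 1 fit, 5 with the covariates and 12 to 63 without 1 mouse. DESeq2 called 2 genes in NMUR1+ and 21 in NMUR1- cells, where edgeR called 0, and leaving out 1 mouse gave 0 to 1 in NMUR1+ cells. NMUR1+ against NMUR1- cells (1123) gave 2605 with limma voom, 2104 with only their 16 libraries, 315 in PBS mice, 110 in NMU mice, 239 with the covariates, 393 without libraries over 20% immunoglobulin and 609 to 1035 without 1 mouse. ILC2 against NMUR1+ (5218) gave 2423 in NMU mice and 2310 with the covariates, and ILC2 against NMUR1- cells (5471) 2836 in NMU mice. The difference of the NMU effect between ILC2 and NMUR1+ cells (98) gave 54 with no filter, 58 with the stricter filter, 516 with DESeq2, 1 with limma voom, 46 with the replicate block, 35 with the covariates, 15 without libraries over 20% immunoglobulin and 30 to 106 without 1 mouse. That between ILC2 and NMUR1- cells (72) gave 387 with DESeq2, 9 with limma voom, 36 with the block, 28 with the covariates, 27 without libraries over 20% immunoglobulin and 20 to 83 without 1 mouse, and that between the CD4 populations (0) 4 with DESeq2 and 1 with the block. Of 90 list calls, 29 held with the estimated correlation. The block also ended the calls of Myb, Zap70, Rgs1 and Ncr1 between the CD4 populations, of Vipr1 and Emcn for ILC2 against NMUR1+ and of Bach2, Krt19, Krt8 and Cpa3 for ILC2 against NMUR1- cells, and Klrg1 (log2 0.72) and Il1rl1 (0.55) passed for ILC2 against NMUR1+ cells. Beside these and those given in the report, it changed no other call of a named gene or called list. Over all genes it kept 970 of the 1123 calls between the CD4 populations, 4818 of 5218 for ILC2 against NMUR1+ and 5100 of 5471 for ILC2 against NMUR1- cells.

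Called genes that turned in PBS mice alone were Cd14 (0.40), Csf3r (1.06) and Lum (0.80) for ILC2 against NMUR1- and Dcn (0.20) for ILC2 against NMUR1+ cells. With the covariates the medians of ribosomal proteins (-0.0619) and macrophages (0.0733) turned in ILC2, those of macrophages in both differences from ILC2 (0.226 and 0.232) and oxidative phosphorylation in the difference from NMUR1- cells (-0.0938) and between NMUR1+ and NMUR1- cells (0.0146).

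The log2 of genes that had not passed turned as follows. For NMU in NMUR1+ cells, Nmur1 was at -0.0087 with upper quartile scaling, -0.0012 with the stricter filter, -0.13 with limma voom, -0.18 with the covariates and -0.45 to 0.36 without 1 mouse. Il13 was at -0.57 with limma voom, -0.0811 with the covariates and -1.09 to 1.99 without 1 mouse, Il4 at 0.88 without libraries over 20% immunoglobulin and -2.80 to 0.52 without 1 mouse, and Il10 at -0.34 to 0.43 without 1 mouse. In NMUR1- cells, with the covariates and without 1 mouse, Nmur1 was at -0.45 and at -0.21 to 0.52, Areg at -0.40 and at -0.12 to 0.96, and Il10 at -0.34 and at -0.15 to 0.43. Nmur1 in ILC2 was at -0.15 to 0.20 without 1 mouse. Between NMUR1+ and NMUR1- cells, Cd3e was at 0.0136 in NMU mice.

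For the difference of the NMU effect between ILC2 and NMUR1+ cells, without 1 mouse Il13 was at -2.32 to 0.18, Il4 at -1.65 to 0.90, Il5 at -1.04 to 0.52 and Nmur1 at -0.24 to 0.46. There Il13 was at 0.0661 and Csf2 at 0.17 with limma voom, Il5 at 0.15 with the covariates and Nmur1 at -0.47 without libraries over 20% immunoglobulin. Between ILC2 and NMUR1- cells, Il5 was at -0.99 to 3.64 and Nmur1 at -0.43 to 0.31 without 1 mouse, and Nmur1 at 0.45 with the covariates and 0.0224 without the ILC2 library of mouse 1. Between the CD4 populations, without 1 mouse Areg was at -0.50 to 0.44, Il10 at -0.79 to 0.21, Il5 at -0.79 to 3.61 and Nmur1 at -0.90 to 0.49. There Areg was at -0.23 with limma voom, Il10 at 0.0816 with the block, and without libraries over 20% immunoglobulin Areg was at -0.21, Il13 at 1.26 and Nmur1 at 0.36.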

Other observations

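The values below were picked after the data were seen, and no explanation was tested. In NMUR1- CD4 T cells the libraries of mice 1, 4 and 5 stood apart in several measures. Immunoglobulin genes and Jchain took 2.83, 5.59 and 3.95% of their counts, against 0.148 to 0.451% in the other 5. Nmur1 was at 7.22, 7.87 and 6.97 CPM against 1.61 to 3.58 CPM, Klrg1 at 171, 187 and 178 against 32.3 to 125.3 CPM, and Areg at 78.9, 89.8 and 82.8 against 14.1 to 27.0 CPM.

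In the NMUR1+ library of mouse 1, Nmur1 was at 6.09 CPM, below the 7.22 CPM of that mouse's NMUR1- library. Its Klrg1 (1192 CPM), Gata3 (1956 CPM) and Il1rl1 (419 CPM) were the highest of the 8 NMUR1+ libraries.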
